A study of Homo sapiens and Drosophila melanogaster with 68 samples.

How the data were processed

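The series holds 68 samples, of which 48 have a peak list. ChIP-seq with a pan-Kacme and an H4Kac antibody was done on S2 cells with and without heat shock (37 °C, 1 h), on HEK293T and on K562, with 2 replicates each. A second HEK293T experiment used the Kacme antibody, 2 µg of an H4Kacme antibody, and input, with 2 replicates each. Peptide competition was done with 2 µL of pan-Kacme antibody and 75 nM peptide (HEK293T, 3 replicates of 4 conditions), with 2 µL of H4Kacme antibody and 100 nM peptide (HEK293T, 2 replicates of 4 conditions) and with 4 µL of pan-Kacme antibody and 75 nM peptide (heat-shocked S2, 2 replicates of 3 conditions). TT-TL-seq and STL-seq of HEK293T, with 1 mM s4U for 5 min, each gave a single table. The remaining ChIP inputs, the CUT&RUN samples of K562 and the TT-TL samples with trichostatin A were not analysed here.

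Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with Bowtie2 (2.2.9 where stated), duplicates were handled with Picard, and peaks were called with MACS2. The builds named are dm6 and hg38 for the earlier experiments and BDGP6 and GRCh38 for the later ones, and regions of different fly builds were never compared. The control library and settings of peak calling are not given in the sources used here. The deposited peak lists give, per library, a fold over background, which the authors made with MACS2 and which is a ratio at the summit. They also give the -log10 p and -log10 q that the authors obtained from MACS2, a deposited score of 10 times the -log10 q, and a summit offset in bp. Every deposited q was at most 0.0499862. Folds and scores depend on the depth of their own library, so they were used only as ranks within 1 library. A list without a peak at a place does not show that the mark was absent there.

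The STL table holds deposited read counts per gene, which the authors did not scale, and a turnover rate constant with its SD, in a time unit not given in the sources used here. It holds 7334 genes and 12905072 reads, with a median of 877 and at least 103 reads per gene. The TT-TL table of the authors holds values named as RPKM, yet each value times the deposited gene length is a whole number of reads (largest distance 7.28e-12), so the values are reads per kilobase and not scaled to the library size. It holds 12266 genes and 28614932 reads, of which 42.6% carry T-to-C changes. Both tables pool the replicates, so no spread between replicates can be had. Genes were matched by symbol, 11757 in the TT-TL and 7102 in the STL table.

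Gene positions came from the RefSeq annotation of GRCh38.p14, which was given without strand. The promoter window planned before the data were examined was therefore replaced by a window of 1 kb around either outermost end of each of 20037 protein-coding genes on the main chromosomes. Ends inside a gene were not used, and no fly gene annotation was used, so fly regions have coordinates only. All other tests, lists and alternatives were fixed before the data were examined, except those named in the closing section as chosen later and the pairwise comparisons of peptides. Peaks on other contigs were left out.

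Reads per library are not given with the lists. Relative depth was recovered by solving the MACS2 fold and p of each peak for the background reads at its summit, with a pseudocount of 1, for peaks with a -log10 p of at most 200 and a fold of at least 1.3. The solved pileup had to be whole within 0.02 reads. The lowest solved value over the peaks of a library was taken as its background reads, so libraries with few peaks rest on few values. This value was 2.78 to 3.85 reads in the first human experiments and 3.10 to 5.03 in the second HEK293T experiment. In the HEK293T competitions it was 2.34 to 3.77. In S2 cells it was 11.2 and 11.9 (Kacme) and 7.98 and 1.04 (heat-shocked Kacme). It was 39.0 for untreated H4Kac replicate 2, 12.7 and 5.16 for heat-shocked H4Kac and 12.9 to 23.1 in the S2 competition. S2_H4Kac replicate 1 gave whole pileups for 4.25% of peaks, so its value was not used. Differences in depth change how many weak peaks pass q, and no list can be corrected for it.

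A region was reproducible where peaks of every replicate of a group met. Regions were shared with at least 1 bp of overlap, and the chance level came from 100 shuffles over the same chromosomes. A gained region has a peak in both heat-shocked and neither untreated library, and a lost region the reverse. In a competition the retained share of a library is the mean share of the peaks of each other no-competitor library that overlap a peak of it. This share depends on the number of peaks in the library, so it and the peak number are not independent results. Peak numbers, shares at gene ends and retained shares were compared with exact permutation tests, two-sided, on means (log2 for numbers). With 2 against 2 the smallest p is 0.333 and with 3 against 3 it is 0.1. The intervals for peptide differences are the lowest and highest pair differences. They cover 90% with 3 against 3 and 66.7% with 2 against 2 if libraries are independent and the groups differ only by a shift. Spreads differed, as with SDs of 16.1 (H4Kac) and 0.0682 (H4Kacme) in the HEK293T pan-Kacme retained shares, so this coverage is not assured. Genes marked in a line alone were tested by Fisher's exact test, two-sided, for 18 lists and both lines against all other genes marked in either line. Benjamini-Hochberg adjustment was made within each family of tests, and the threshold was 0.05.

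For nascent and short RNA, genes marked in both replicates were compared with genes marked in neither by the difference of medians, and within marked genes by Spearman's rho with the mean rank of the strongest peak, with 100000 permutations (10000 for alternatives). TT-TL values were taken as log2 of the value plus a pseudocount of 1. The difference of rho between Kacme and H4Kac has a 95% interval from 1000 resamplings of genes (seed 11).

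The lists were heat shock and chaperone, immediate early, cytosolic ribosomal protein, replication-dependent histone, lysine acetyltransferase, deacetylase and BET, lysine methyltransferase and demethylase, transcription machinery and pausing, glycolysis, proteasome, erythroid, other blood lineage, kidney and HEK293 developmental, neuronal, other tissue-specific, olfactory receptor, C2H2 zinc finger, p53 target and cell cycle genes. Named genes were the 10 per direction with the highest mean percentile of their strongest peak among those marked in all libraries of a set and none of the other, and up to 4 per list. For transcription they were the 10 highest marked and 10 highest unmarked genes. For competition they were the 10 highest without competitor and up to 10 still marked in at least 2 H4Kacme-peptide libraries. For flies they were the 5 strongest gained and 5 strongest lost regions. The text prints part of them, and genes on unplaced contigs were left out.

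Alternatives changed 1 choice at a time: peaks with a -log10 q of at least 5, lists shortened to the length of the shortest by -log10 p, 50% overlap of the shorter interval, summits within 250 bp, windows of 250 bp and 2 kb, pseudocounts of 0.1 and 10, genes above the 25th percentile, -log10 p in place of fold, input peaks removed, each replicate left out, and replicate number as a block. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The code was tested on simulated data: 0 of 1200 overlap calls differed from a direct count, 100% of 4890 backgrounds were recovered within 1%, 200 of 200 planted genes were found, and 5% of 2000 exact tests without a difference gave p at or under 0.05. No pair of peak lists was identical (0 pairs).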

Results

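Acetyl-methyllysine (Kacme) is a lysine side chain that carries an acetyl and a methyl group together. The series mapped it by chromatin immunoprecipitation and sequencing (ChIP-seq), beside acetylated histone H4 (H4Kac), and asked where it lies relative to the starts of active genes. The cells were S2, a fly line with features of blood cells, HEK293T, a human embryonic kidney line, and K562, a human leukaemia line with erythroid features. A human gene was called marked where a peak lay within 1 kb of either of its annotated ends. A percentile gives the rank of a gene's strongest peak, by its deposited fold, within 1 library, as mean ± SD over 2 libraries unless stated. The labels do not say that replicates came from separate cultures, so a p from comparing libraries measures only the spread between these samples, which may be technical. A p from a test over genes measures the spread over genes and not between samples.

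In HEK293T cells Kacme and H4Kac lay at the ends of largely shared genes. Of 20037 protein-coding genes, 10488 were marked in both replicates with both antibodies, 384 in both Kacme replicates and neither H4Kac replicate, and 177 in both H4Kac replicates and neither Kacme replicate. The genes with Kacme but no H4Kac peak were led by TTI2, a partner of kinase-stabilising chaperones (chromosome 8, 33498722 to 33513135), at percentile 99.6 ± 0.0823. They also held the zinc finger gene ZNF175 (99.1 ± 0.109) and SLC7A11, which encodes a cystine transporter (chromosome 4, 138164097 to 138242349; 96.9 ± 1.09). Genes with H4Kac but no Kacme peak included the neural transcription factor gene SOX1 (80.6 ± 8.26) and LTBR, the lymphotoxin beta receptor gene (90.5 ± 0.00809), and both calls ended with windows of 250 bp and of 2 kb.

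In K562 cells 11091 genes were marked in both replicates with both antibodies, 74 with Kacme and not H4Kac, and 134 the reverse. CYLD, a deubiquitinase gene (chromosome 16, 50742086 to 50801935; 68.4 ± 4.62), and RNF151 (84.2 ± 0.0384) had Kacme but no H4Kac peak. The proton-sensing receptor gene GPR4 (95.9 ± 1.48) and CD14, a monocyte marker (72.5 ± 6.87), had H4Kac but no Kacme peak. The F-box gene FBXO46 (chromosome 19, 45710629 to 45733177) had H4Kac and no Kacme peak in both lines, at 91.7 ± 6.28 in HEK293T and 98.5 ± 0.927 in K562. With windows of 250 bp and of 2 kb the calls for RNF151, GPR4 and, in both lines, FBXO46 ended, and that for CD14 ended with 250 bp.

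Regions found in both replicates were compared between the antibodies along the whole genome. In S2 cells 7886 of 8265 Kacme regions (95.4%) overlapped an H4Kac region and 6657 of 7828 H4Kac regions (85.0%) overlapped a Kacme region. In HEK293T the shares were 18832 of 33163 (56.8%) and 19374 of 24530 (79.0%). In K562 they were 32263 of 36517 (88.4%) and 31573 of 43800 (72.1%). Shuffled regions overlapped in 16.2% and 15.1% of cases in S2 and in at most 3.09% in the human lines. The HEK293T Kacme share was 35.7% without HEK_Kacme replicate 1 and 33.7% without replicate 2. The HEK293T H4Kac share was 52.2% without HEK_H4Kac replicate 2, and the K562 H4Kac share 46.0% without K562_H4Kac replicate 1. A region then needs a peak in a single library, so more regions enter the comparison.

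S2 cells gave 9769 ± 223 Kacme and 8664 ± 150 H4Kac peaks per library (SD, n = 2), a log2 ratio of 0.17. HEK293T gave 64287.5 ± 3542 Kacme and 43081 ± 5272 H4Kac peaks, a log2 ratio of 0.58, and K562 gave 60835 ± 748 and 74780 ± 6495, a log2 ratio of -0.30. Every exact two-sided p was 0.333 (adjusted 0.381 over 8 tests), the smallest that 2 libraries against 2 allow, so no difference in number could pass 0.05. With only peaks at a -log10 q of 5 or more the ratios were 0.02 in S2, 0.38 in HEK293T and -0.15 in K562.

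Peaks of both marks lay at gene ends far more often than shuffled peaks. In HEK293T 30.9 ± 1.22% of Kacme and 39.2 ± 3.57% of H4Kac peaks were at gene ends, and in K562 27.6 ± 0.331% and 22.7 ± 1.46% (SD, n = 2), against 3.38% to 3.63% after shuffling. The middles of the same genes held 3.64% to 4.32% of peaks. A gene has a window at each end but a single one at its middle. No shuffled level was made for middles, so the shuffled values above do not apply to them. Of 11014 genes longer than 20 kb, HEK_Kacme replicate 1 had a peak at a single end of 7102, at both ends of 416 and at the middle of 401. Kacme minus H4Kac was -8.31 percentage points in HEK293T and 4.84 in K562 (exact two-sided p = 0.333 for each, the smallest possible; adjusted 0.333 over 2 tests). With lists of equal length the HEK293T difference turned to 0.335 points (exact p = 0.667) and the K562 difference fell to 1.40 (exact p = 0.333). The HEK293T difference was -4.73 with a -log10 q of 5 or more and -5.30 with a 2 kb window.

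Kacme marked 11652 of 20037 genes in both HEK293T replicates, and the share of a list was not tested against it. The counts were 78 of 79 cytosolic ribosomal protein genes, 30 of 30 cell cycle genes, 29 of 29 genes of the transcription machinery and pausing, and 29 of 30 lysine acetyltransferase, deacetylase and BET genes. They were 30 of 34 proteasome genes, 17 of 18 glycolysis genes, 20 of 24 heat shock and chaperone genes, 24 of 30 lysine methyltransferase and demethylase genes, 23 of 26 immediate early genes and 15 of 20 p53 targets. High examples were RPL29 (99.9 ± 0.00464), the DNA helicase gene MCM2 (99.8 ± 0.0649), the acetyltransferase gene KAT7 (99.6 ± 0.331), PSMD7 (99.9 ± 0.105) and the ubiquitin ligase gene MDM2 (98.4 ± 0.106). DNAJB1, HK1, PSMA6 and AEN were unmarked in HEK293T Kacme libraries, but with a 2 kb window DNAJB1 was marked in both and AEN in at least 1. Only the outermost annotated ends were used, so a start inside these genes was not examined.

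Among replication-dependent histone genes, which are transcribed in S phase, 46 of 69 were marked by Kacme and 26 by H4Kac in HEK293T, and 50 by each antibody in K562. The histone pair H2AC17 and H2BC17 stood at 99.5 ± 0.0177 in HEK293T. C2H2 zinc finger genes were marked in 355 of 509 cases by HEK293T Kacme, and olfactory receptor genes, which are active in the nose, in 1 of 392. Of genes specific to other tissues 7 of 31 were marked, among them the muscle gene ACTN2 (98.2 ± 0.305), while the liver gene ALB was unmarked. The plot of the 18 lists gives all 4 groups.

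**Figure D1:**
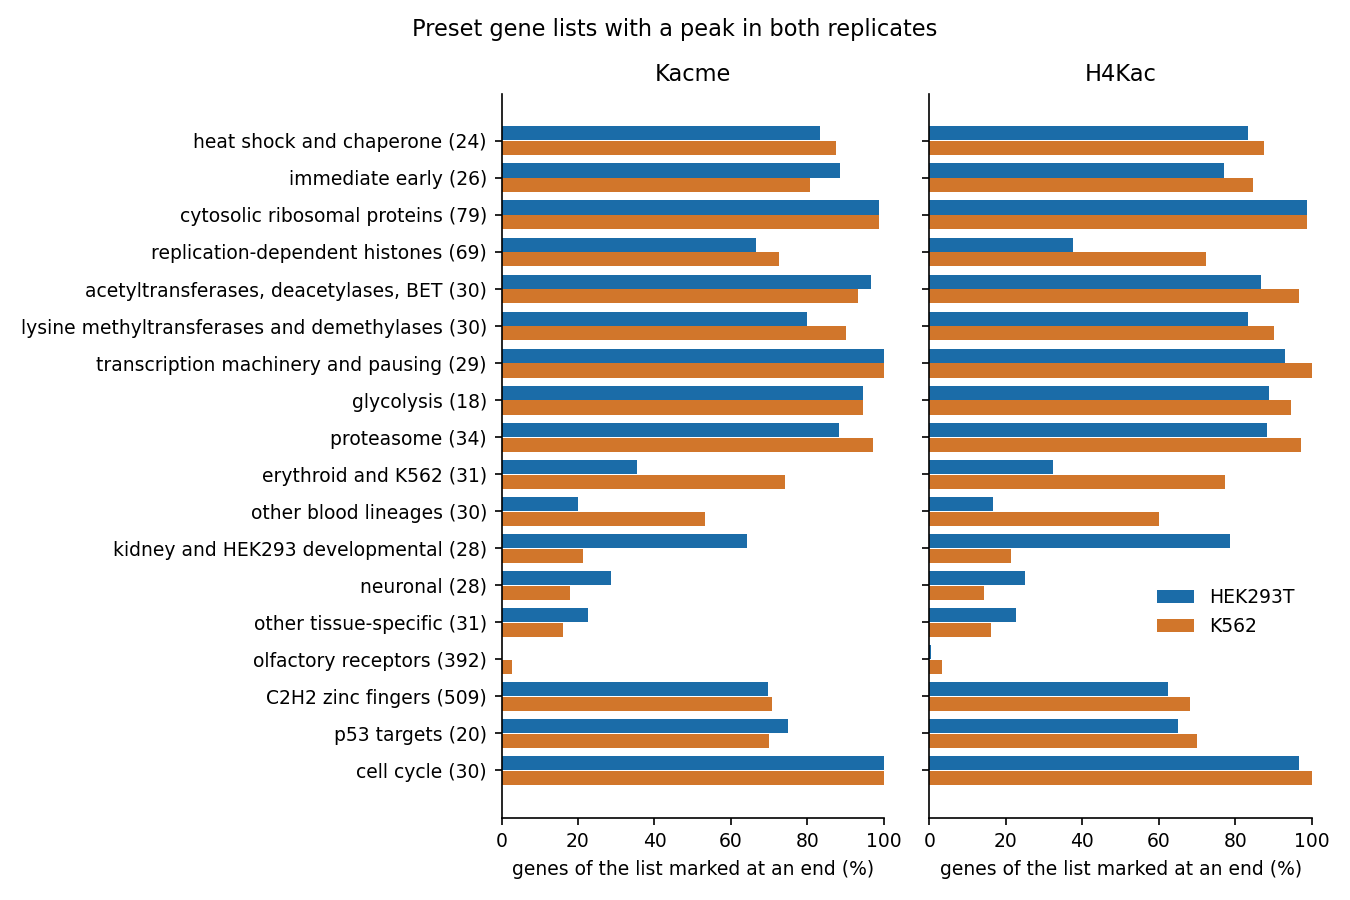
Bars give the percent of the genes of each of the 18 lists (vertical axis) that were marked at an end in both replicates, for HEK293T (blue) and K562 (orange), in a panel each for Kacme and H4Kac. Ribosomal protein genes stood at 78 of 79 in all 4 groups, while 11 of 31 erythroid genes were marked by Kacme in HEK293T and 23 of 31 in K562.

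An antibody against H4Kacme, acetyl-methyllysine on histone H4, was used beside the Kacme antibody in the second HEK293T experiment. All 1828 genes marked by H4Kacme in both replicates were also marked by Kacme in both, and 6129 genes had Kacme in both replicates and H4Kacme in neither. Among the latter were LRP6, a Wnt co-receptor gene (Kacme percentile 99.5 ± 0.197), and TMPO, which encodes a nuclear envelope protein (99.3 ± 0.397). The TMPO call ended with a 2 kb window, and with 250 bp 1 Kacme library marked it. A peak at chromosome 9, 99221877 to 99223311, between ALG2 and SEC61B, stood at 99.7 ± 0.0520. Ribosomal protein genes made up 46 of the H4Kacme genes and 78 of the Kacme genes, of 79, and cell cycle genes 10 and 30, of 30. No gene of the erythroid, other blood, kidney, neuronal or olfactory lists was marked by H4Kacme in both replicates.

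Of 2423 H4Kacme regions 2289 (94.5%) overlapped a Kacme region, and 2218 of 19746 Kacme regions (11.2%) overlapped an H4Kacme region. The Kacme antibody gave 28626 ± 492 peaks, the H4Kacme antibody 4057.5 ± 327, and the inputs 75 and 159 (SD, n = 2; exact two-sided p = 0.333 for each pair, adjusted 0.381 over 8 tests). At gene ends lay 45.8 ± 1.06% of Kacme, 63.2 ± 1.01% of H4Kacme and 0% of input peaks. With lists of equal length 51.8% of Kacme regions overlapped an H4Kacme region, and without HEK2_H4Kacme replicate 1 19.1% did. Of the Kacme regions of the first experiment 54.9% overlapped those of the second, and 87.9% of the second overlapped the first.

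Both replicates of HEK293T and neither of K562 marked 1373 genes with Kacme, and the reverse held for 826, while 10012 were marked in both lines. The kidney and HEK293 developmental genes marked in HEK293T alone included HOXD11, a homeobox gene of the embryonic kidney (chromosome 2, 176107280 to 176115679; 98.0 ± 0.339), and SIX2, a factor of nephron progenitors (93.2 ± 6.46). LYL1, a blood transcription factor gene, was marked in K562 alone (chromosome 19, 13099033 to 13102858; 96.8 ± 0.736). So were the erythroid regulator genes TAL1 (95.4) and GATA1 (72.2), which, like the list members named next, were chosen after their values were seen.

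By preset list, 12 of the 18 kidney and HEK293 developmental genes marked in a line were marked in HEK293T alone (66.7%, against 10.5% of other marked genes; Fisher's exact two-sided p = 1.93e-08, adjusted 3.48e-07 over 36 tests). K562 alone marked 11 of 18 genes of other blood lineages (61.1% against 6.30%; Fisher p = 1.39e-09, adjusted 5.02e-08), among them RUNX1, CSF1R and CD3D. It alone marked 11 of 23 erythroid genes (47.8% against 6.30%; Fisher p = 4.40e-08, adjusted 5.29e-07), including HBG1, HBG2 and GYPE. Of olfactory receptor genes 7 of 11 were marked in K562 alone (63.6% against 6.33%; Fisher p = 1.10e-06, adjusted 9.88e-06), and OR51B5 stood at 85.3 ± 6.94. Genes of a list can be neighbours, as 4 of these 7 receptor genes, HBG1 with HBG2, HOXA10 with HOXA11 and DLX5 with DLX6 are, so the list tests count genes that are not independent and their p-values are too small as a measure of chance. Ribosomal protein genes were marked in HEK293T alone in 0 of 78 cases (against 10.7%; Fisher p = 0.000288, adjusted 0.00208). The other 31 tests did not pass 0.05, among them neuronal genes in HEK293T alone (4 of 10, adjusted 0.0702). The neuronal test passed without HEK_Kacme replicate 1 (adjusted 0.0102), HEK_Kacme replicate 2 (0.000515) or K562_Kacme replicate 2 (0.0160). Without HEK_Kacme replicate 2 the tests past 0.05 numbered 8 instead of 5, and with a -log10 q of 5 or more the genes of K562 alone numbered 1287.

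Strong single genes outside the lists also separated the lines. HEK293T alone marked CEP15 (chromosome 3, 62319022 to 62336213; 99.9 ± 0.0239), the antiviral ligase gene HERC5 (99.9 ± 0.0196) and OLIG2, a neural transcription factor gene (chromosome 21, 33025935 to 33029185; 99.6 ± 0.154). The peak at chromosome 22, 45413015 to 45414780, lay between RIBC2 and the meiotic cohesin gene SMC1B (99.9 ± 0.0557). K562 alone marked GTF2IRD2 (chromosome 7, 74796151 to 74851605; 99.7 ± 0.124), the complement receptor gene VSIG4 (99.6 ± 0.00407) and PTPN7, a phosphatase gene of blood cells (chromosome 1, 202147013 to 202161588; 99.1 ± 0.0947), but with a 2 kb window both HEK293T libraries marked PTPN7. Of the 23 erythroid genes marked in a line, 11 were marked in both replicates of both lines. Among them was GFI1B, a blood repressor gene, at 99.8 ± 0.0222 in HEK293T, by a peak that also lies at the end of TSC1. With a 250 bp window GFI1B was marked in 1 fewer HEK293T than K562 library.

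H4Kac marked 1368 genes in HEK293T alone and 1130 in K562 alone, and 8 of 36 tests passed. Kidney and HEK293 developmental genes in HEK293T alone numbered 16 of 22 (72.7% against 10.3%; Fisher's exact two-sided p = 7.57e-12, adjusted 1.64e-10). In K562 alone were 14 of 19 other blood (73.7% against 8.54%; Fisher p = 9.12e-12, adjusted 1.64e-10), 12 of 24 erythroid (adjusted 1.48e-06), 11 of 13 olfactory receptor (adjusted 1.51e-09) and 14 of 52 histone genes (26.9% against 8.56%; p = 9.16e-05, adjusted 0.00066). Ribosomal protein genes were marked in 0 of 78 cases in HEK293T alone (adjusted 0.00172) and in K562 alone (adjusted 0.00779). Neuronal genes, among them NEUROG2 and POU3F2, were marked in HEK293T alone in 5 of 9 cases (55.6% against 10.4%; adjusted 0.00559). The neuronal call was lost with a -log10 q of 5 or more (adjusted 0.675), with lists of equal length (0.123) and with a 250 bp window (0.232), and at a -log10 q of 5 or more the genes of K562 alone numbered 1849. For Kacme the histone genes of K562 alone numbered 5 of 52 (adjusted 0.574), and the difference between the antibodies was not tested. High genes of H4Kac alone in a line were EPHX4 in HEK293T (99.9 ± 0.0241) and the platelet receptor gene F2RL3 in K562 (99.7 ± 0.0456).

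Genes with Kacme at an end had more nascent RNA in HEK293T. Nascent RNA came from TT-TL-seq, in which RNA labelled for 5 min with 4-thiouridine (s4U) is sequenced, and its table gives no replicates. The highest marked genes were the stress response regulator ATF4 (3731 reads per kilobase), PTMA (2606), the immediate early gene JUN (2438) and the ribosomal protein gene RPS2 (2012). Genes without a Kacme peak in either replicate included HNRNPH1 (338 reads per kilobase) and the homeobox gene HOXD10 (225). By list the median was 9.29 log2 reads per kilobase for ribosomal protein, 7.25 for cell cycle, 7.12 for heat shock, 5.20 for zinc finger and 2.72 for other blood lineage genes. These medians cover only genes with a nascent value: 74 of 79, 29 of 30, 21 of 24, 353 of 509 and 9 of 30 genes, in that order.

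The median of 9920 marked genes was 5.48 log2 reads per kilobase and that of 1131 unmarked genes 2.80, a difference of 2.68 (permutation test across genes, two-sided p = 1e-05, the smallest that 100000 resamples give; adjusted 2e-05 over 12 tests). For H4Kac the medians were 5.49 for 9453 marked and 3.40 for 1315 unmarked genes, a difference of 2.09 (permutation p = 1e-05, adjusted 2e-05). Across marked genes, which are not independent replicates, peak rank and nascent RNA had a Spearman rho of 0.308 for Kacme (Pearson r 0.305) and 0.215 for H4Kac (0.219), each with a permutation p of 1e-05 and adjusted 2e-05. Over 8982 genes with both marks rho was 0.116 higher for Kacme than for H4Kac (95% interval 0.0963 to 0.136 from resampled genes). The Kacme libraries of the second experiment gave a rho of 0.129, and its H4Kacme libraries 0.0125 and 0.0247. Among genes above the 25th percentile of nascent RNA the median differences were 0.71 for Kacme and 0.65 for H4Kac, with a pseudocount of 10 the Kacme difference was 1.74, and with a -log10 q of 5 or more the H4Kac rho was 0.141. The table lists 85.1% of genes marked by Kacme and 15.5% of unmarked genes, so the unmarked genes compared are those with detected RNA.

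**Figure D2:**
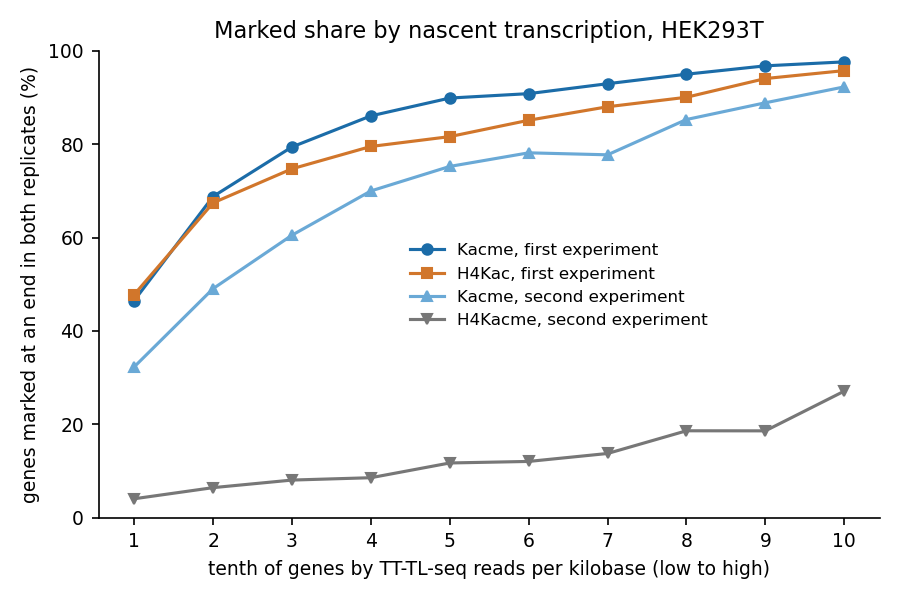
The share of genes marked in both replicates (vertical axis, percent) is drawn for each of 10 equal groups of TT-TL genes by nascent reads per kilobase (horizontal axis), with a line each for Kacme and H4Kac of the first experiment and Kacme and H4Kacme of the second. From the lowest to the highest group the share ran from 46.5% to 97.6% for Kacme and from 4.08% to 27.1% for H4Kacme.

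Short capped RNA near gene starts was measured by STL-seq, whose table gives reads and a turnover rate constant per gene, in a time unit not given in the sources used here. High rate constants among Kacme-marked genes were those of the RAS-like gene MRAS (0.184) and the kinase gene MKNK2 (0.175), and among unmarked genes that of PLB1 (0.142). Marked genes had more STL reads, with medians of 9.84 log2 reads for 6472 marked and 9.08 for 397 unmarked genes (difference 0.76, permutation two-sided p = 1e-05, adjusted 2e-05 over 12 tests), and 0.44 for H4Kac (adjusted 2e-05). Across genes the rho of STL reads with peak rank was 0.141 for Kacme (adjusted 2e-05) and 0.0153 for H4Kac (adjusted 0.236). The H4Kac value turned to -0.00728 with a -log10 q of 5 or more and to -0.0116 with a 250 bp window, and passed with -log10 p in place of fold (0.0330, adjusted 0.0126). Among genes above the 25th percentile the median differences in reads were 0.44 and 0.29. STL-seq values exist for 55.5% of genes marked by Kacme and 5.45% of unmarked genes, and for 54.0% and 7.46% with H4Kac. The unmarked genes compared, for reads and for rates, are thus a small part with detected RNA.

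Rate constants differed little. Their median was 0.0464 in Kacme-marked and 0.0502 in unmarked genes, a difference of -0.0038 (permutation two-sided p = 0.00293, adjusted 0.00439 over 12 tests), and rho with peak rank was -0.0361 (p = 0.00368, adjusted 0.00491). The median call was lost with a 2 kb window (-0.00207, adjusted 0.187), the median difference was -0.00235 with a 250 bp window (adjusted 0.0159), and the rho call was lost with a -log10 q of 5 or more (-0.0190, adjusted 0.189) and among genes above the 25th percentile (-0.0258, adjusted 0.0776). For H4Kac the difference of -0.00215 (p = 0.0501, adjusted 0.0546) and the rho of -0.0255 (p = 0.0471, adjusted 0.0546) did not pass. Both passed with a 250 bp window (adjusted 0.0093 and 0.0385). The H4Kac median difference fell to -0.00111 without HEK_H4Kac replicate 1 (adjusted 0.210) and to -0.00143 with a 2 kb window (adjusted 0.235), and the rho to -0.00424 with a -log10 q of 5 or more (adjusted 0.776). Rates under 0.005 were listed for 50 genes, and 12 of them, such as C12orf57 with the small RNA gene RNU7-1, hold or adjoin an annotated small RNA gene.

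Heat shock of S2 cells, at 37 °C for 1 h, was compared with untreated cells by regions in dm6 coordinates. The strongest region with Kacme peaks in both heat-shocked replicates and neither untreated replicate was chromosome 3L, 17797808 to 17799799 (percentile 99.6 ± 0.274), with folds of 40.3 and 26.2. The next was chromosome 2R, 12952993 to 12955602 (98.7 ± 1.37). The strongest of the reverse kind was chromosome 3R, 15286146 to 15286896 (99.6 ± 0.0333), with folds of 33.1 and 34.2 in untreated cells, followed by chromosome 2L, 8730242 to 8731505 (97.9 ± 1.97). For H4Kac a region at chromosome 3L, 17795696 to 17799871, was gained (99.7 ± 0.106), which holds the strongest gained Kacme region, and chromosome 3L, 18240347 to 18243318, was lost (94.7 ± 0.666).

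In all, 416 Kacme regions were gained and 2589 lost, and 813 H4Kac regions were gained and 959 lost. Of the gained and lost Kacme regions 72 (17.3%) and 362 (14.0%) overlapped H4Kac regions of the same kind. Other ways to part the 4 Kacme libraries into 2 and 2 gave 0 and 195 or 182 and 10 regions, and no p from 2 against 2 can pass 0.05. The heat-shocked Kacme libraries held 15381 and 4265 peaks, against 9769 ± 223 (SD, n = 2) in untreated cells, with 7.98 and 1.04 background reads against 11.2 and 11.9. The heat-shocked H4Kac libraries had 12.7 and 5.16 background reads, against 39.0 in untreated replicate 2, the only untreated H4Kac library with a usable value. Depth therefore limits the H4Kac counts too. The direction for Kacme differed between the 2 heat-shocked libraries. Compared 1 library with 1, heat-shocked replicate 1 gained 6509 and 6607 regions and lost 3717 and 3417 against the 2 untreated libraries, while replicate 2, the shallow one, gained 800 and 917 and lost 7596 and 7342. For H4Kac replicate 1 gained 1529 and 1649 and lost 1676 and 1706, and replicate 2 gained 2613 and 2769 and lost 1871 and 1931. Without S2_HS_Kacme replicate 2 there were 6187 gained and 2608 lost regions and the log2 ratio of peak number turned from -0.27 (exact p = 1) to 0.66, and without replicate 1 there were 737 and 6119. H4Kac regions gained and lost were 2466 and 1422 without S2_HS_H4Kac replicate 1, and 1427 and 1251 without replicate 2. A gained region then needs a peak in 1 library and a lost region still needs 2, which by itself raises the gained number. With a fold of at least 4 the counts were 114 and 930 for Kacme and 141 and 116 for H4Kac, with a -log10 q of 5 or more 116 Kacme and 481 H4Kac regions were gained, with lists of equal length 1564 Kacme regions were lost and 378 H4Kac regions gained, and by summits within 250 bp 1390 Kacme regions were gained and 2474 H4Kac regions gained and 1983 lost.

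**Figure D3:**
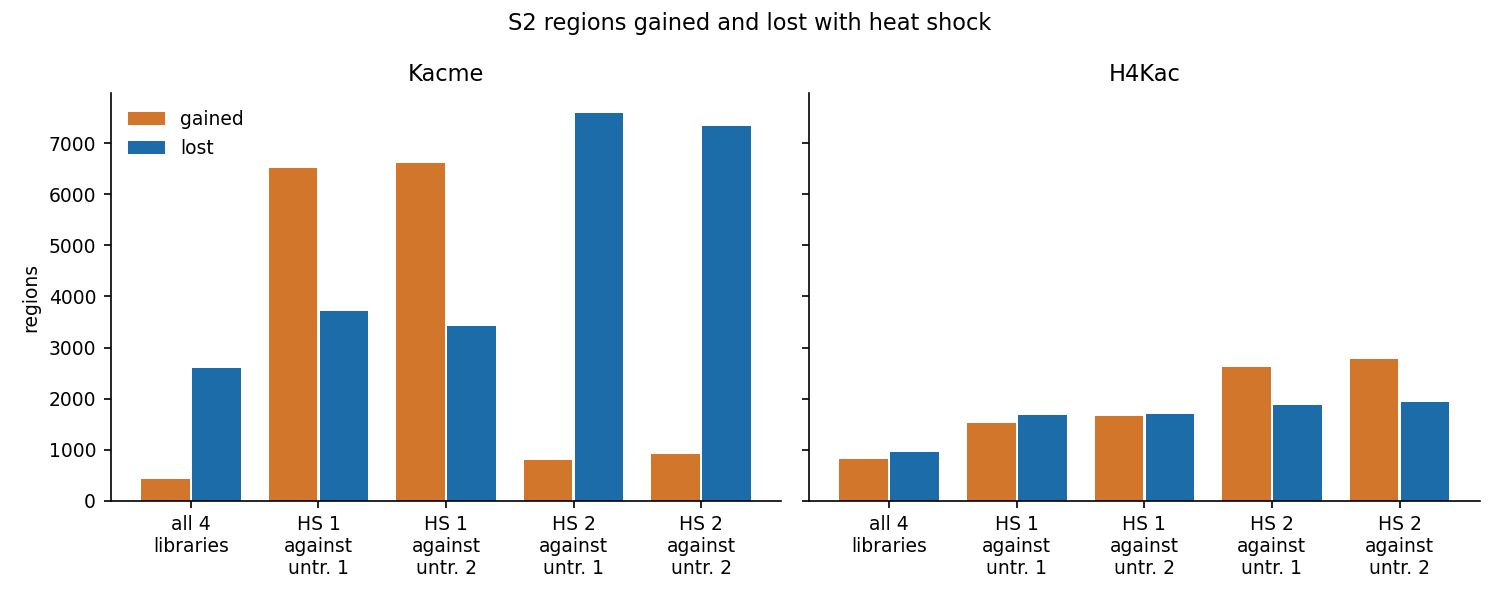
Bars give the number of regions gained (orange) and lost (blue) with heat shock, for all 4 libraries and for each heat-shocked library (HS) against each untreated library (untr.), in a panel each for Kacme and H4Kac. For Kacme the lost regions outnumber the gained ones with all libraries (2589 against 416), and the gained ones outnumber the lost with heat-shocked replicate 1 against untreated replicate 1 (6509 against 3717).

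Peptides with acetyl-lysine, Kpr (propionyl-lysine by the usual abbreviation) or acetyl-methyllysine of histone H4 were added as competitors at 75 nM in HEK293T pan-Kacme ChIP. Peaks at UBB, a ubiquitin gene (chromosome 17, 16380779 to 16382745), TAF7, a gene of the TFIID complex, and EIF4A2, a translation factor gene (99.9 ± 0.0203, n = 3), were among the highest without competitor, and UBB was at percentile 100 ± 0 (n = 3). With the H4Kacme peptide EIF4A2 and the histone mRNA factor gene SLBP had no peak in any of 3 libraries, and TAF7, MCM7, AP4M1 and CHAF1A, also among the 10 highest without competitor, had a peak in 1 of 3. Genes marked in all 3 replicates numbered 3055 without competitor, 3284 with the H4Kac peptide, 3964 with the H4Kpr peptide and 2 with the H4Kacme peptide. In 2 or more of the 3 replicates they numbered 5473, 5868, 6120 and 3. The remaining genes were UBB and COX19, a gene of mitochondrial copper handling (chromosome 7, 964852 to 975549; 64.7 ± 11.5, n = 3), and SURF6 was marked in 2 of the 3 libraries. Ribosomal protein genes marked in all replicates numbered 57, 60, 69 and 0 of 79, cell cycle genes 14, 16, 19 and 0 of 30, and zinc finger genes 117, 136, 164 and 0 of 509.

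Of the peaks of the no-competitor libraries 0.227 ± 0.0682% were retained with the H4Kacme peptide, against 61.6 ± 17.9% between no-competitor replicates, 65.1 ± 16.1% with the H4Kac peptide and 67.5 ± 3.15% with the H4Kpr peptide (SD, n = 3). The H4Kacme peptide libraries fell by 64.5 percentage points against the 9 others, in all 3 libraries (exact two-sided p = 0.00455, the smallest of 220 assignments; adjusted 0.0182 over 8 tests). Peak numbers differed from the 9 others by -7.99 on the log2 scale (exact p = 0.00455, adjusted 0.0182). They were 34.7 ± 13.1 with the H4Kacme peptide and 7946 ± 2911 without competitor (SD, n = 3). A list this short can overlap few peaks, so the retained share largely restates the peak number. Among no-competitor libraries too, the one with 5562 peaks retained 46.0% and the one with 11190 peaks 81.2%. Lists of equal length were not compared in the competitions. Against no competitor alone the retained share differed by -61.4 points and the log2 peak number by -7.86 (each exact p = 0.1, the smallest for 3 against 3; adjusted 0.2). Both calls against the 9 others end when any H4Kacme-peptide library is left out (adjusted exact p = 0.0727) and within replicate blocks (adjusted 0.0625), where fewer assignments exist. Background reads were 2.68 ± 0.383 with the H4Kacme peptide and 2.93 ± 0.119 without competitor (SD, n = 3). Of the peaks left with the H4Kacme peptide, 23.1% to 33.3% overlap an input peak of the second experiment.

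The H4Kac and H4Kpr peptides, at the same dose, did not differ detectably from each other or from no competitor in retained share. H4Kac minus H4Kpr was -2.34 points (90% interval -15.3 to 18.7, exact two-sided p = 1), while H4Kac minus H4Kacme was 64.9 (55.5 to 83.6) and H4Kpr minus H4Kacme 67.2 (64.8 to 70.9), each with an exact p of 0.1, the smallest possible. These pairwise comparisons of peptides were chosen after the data were seen, and a p that misses the threshold does not show that peptides act alike. Against no competitor the differences were 3.52 and 5.86 points (exact p = 0.7 and 0.7, adjusted 0.7), and without HEKcomp_panKacme_nocomp replicate 1 they turned to -2.42 and -0.307.

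**Figure D4:**
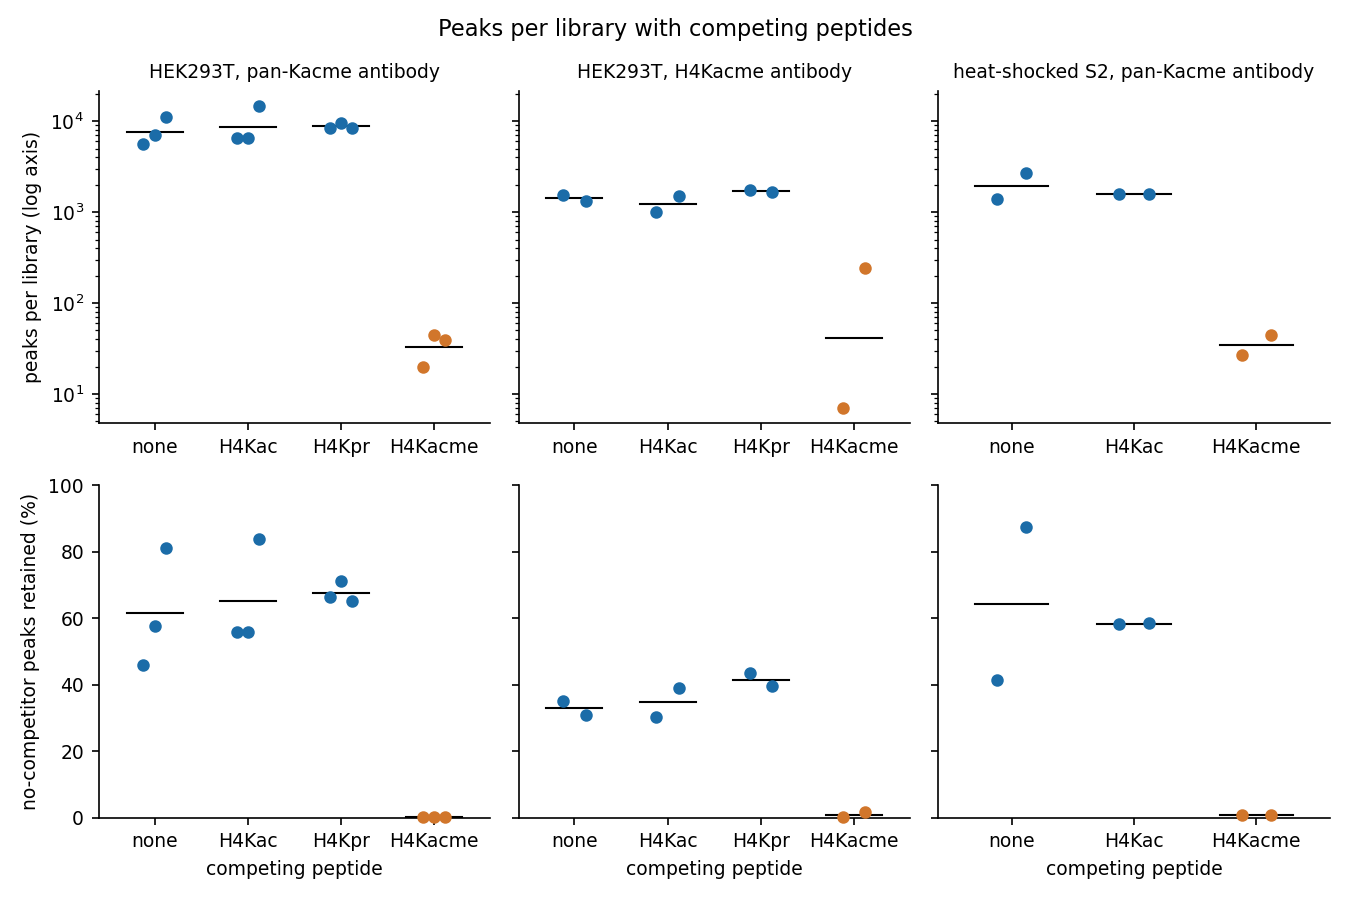
Points are libraries, with peaks per library (log axis) in the upper panels and the percent of no-competitor peaks retained in the lower panels, by competitor, for HEK293T pan-Kacme, HEK293T H4Kacme antibody and heat-shocked S2 pan-Kacme; lines are geometric means above and means below. Libraries with the H4Kacme peptide (orange) retained at most 1.75% in every set, against 33.0% or more on average without competitor.

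With the H4Kacme antibody in HEK293T and 100 nM peptide, the same kind of loss was seen at fewer genes. The highest genes without competitor were UBB (100 ± 0), the DNA damage gene MDC1 (chromosome 6, 30699807 to 30717281; 99.5 ± 0.241) and CBX5, which encodes heterochromatin protein HP1 alpha (98.0 ± 1.20). None of them had a peak with the H4Kacme peptide. Genes marked in both replicates numbered 439 without competitor, 402 with H4Kac, 582 with H4Kpr and 0 with H4Kacme peptide, and no gene of any of the 18 lists was marked in both with the last. Without replicate 1 or 2 of a group the genes of the other library numbered 813 or 933, 871 or 643, 948 or 1204, and 1 or 0. Retained shares were 33.0 ± 3.10% without competitor, 34.7 ± 6.31% with H4Kac, 41.5 ± 2.88% with H4Kpr and 0.927 ± 1.17% with H4Kacme peptide (SD, n = 2). The difference of -35.5 points to the 6 others did not pass after adjustment (exact two-sided p = 0.0357, the smallest of 28 assignments; adjusted 0.143 over 8 tests). The log2 peak number differed by -5.14, and by -2.58 without HEKcomp_H4Kacme_H4Kacmecomp replicate 1. H4Kac minus H4Kpr was -6.83 points (66.7% interval -13.3 to -0.337, exact p = 0.333, the smallest possible), H4Kac minus H4Kacme 33.8 (28.5 to 39.0) and H4Kpr minus H4Kacme 40.6 (37.7 to 43.5). The H4Kac difference from no competitor, 1.71 points (exact p = 1), turned to -2.75 without HEKcomp_H4Kacme_H4Kaccomp replicate 2. In this set 11.3% to 27.8% of peaks lay on chromosome 13 where the H4Kacme peptide was absent, and 191 of 241 peaks (79.3%) in H4Kacme-peptide replicate 2.

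In heat-shocked S2 cells pan-Kacme peaks numbered 1381 and 2707 without competitor, 1597 and 1579 with the H4Kac peptide, and 27 and 45 with the H4Kacme peptide at 75 nM. The H4Kacme peptide left 0.776 ± 0.0648% of no-competitor peaks, against 64.4 ± 32.4% between no-competitor replicates and 58.4 ± 0.241% with H4Kac (SD, n = 2). The difference to the 4 others was -60.6 points (exact two-sided p = 0.0667, the smallest of 15 assignments; adjusted 0.2 over 6 tests), and -5.65 in log2 peak number (same p). H4Kac minus H4Kacme was 57.6 points (66.7% interval 57.4 to 57.8, exact p = 0.333, the smallest possible). H4Kac minus no competitor was -0.28 in log2 peak number (exact p = 1), and without S2comp_panKacme_nocomp replicate 2 it turned to 0.20.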

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

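The minimum fold of 4 in the heat shock comparison, the comparison of 1 heat-shocked with 1 untreated library, the leaving out of chromosomes 9 and 13, the reads behind low rate constants and the other splits of the competition libraries were chosen only after the results were seen.

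With Kacme, 2589 regions were lost and 416 gained after heat shock of S2 cells, or 6.22 lost per gained region. A single shallow library is consistent with this direction: with heat-shocked replicate 1 alone against each untreated library alone the value was 0.571 and 0.517 lost per gained region, and with replicate 2, the shallow one, 9.50 and 8.01. Leaving replicate 2 out of the main comparison does not test this, since a gained region then needs 1 library and a lost region 2. The shallow library bears on the gained number, since a gained region needs a peak in both heat-shocked libraries (416, against 6187 without it). It does not account for the lost number, since a region counts as lost only where both lack a peak. Of 8265 untreated regions 68.4% have a peak in heat-shocked replicate 1 and 2608 do not, and 2589 lack one in both heat-shocked libraries. Fewer reads in both heat-shocked libraries cannot be told apart from a loss of the mark at those regions, since heat-shocked replicate 1, with 7.98 background reads, also lay below the untreated libraries at 11.2 and 11.9. Yet that replicate held 15381 peaks, against 9927 and 9611 in the untreated libraries. Median peak width was 356 and 262 bp in the heat-shocked and 648 and 671 bp in the untreated Kacme libraries. How width bears on gained and lost counts was not tested. With a fold of at least 4 there were 8.16 lost per gained region, but the bound set for that test was wrong. A gained region then still needs a peak in the shallow library, with a fold of at least 4, so the ratio cannot decide. Lost regions lay lower in the untreated list (median percentile 37.4) than kept regions (66.0). A response of the cells to heat shock, which the design names, stays among the open explanations and was not tested apart from depth.

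In the HEK293T competition with the H4Kacme antibody, H4Kacme-peptide replicate 2 held 241 peaks, of which 191 lay on chromosome 13, between 61752018 and 91316510. On average 1.75% of the peaks of a no-competitor library overlapped a peak of this replicate, so few no-competitor peaks were retained in it. No-competitor peaks on chromosomes 9 and 13 lay at gene ends in 11.6% of 699 cases, against 66.0% of 2186 elsewhere. For these no-competitor peaks the difference of -54.4 percentage points (95% interval -57.3 to -51.1) goes with a locally raised read background in those libraries. Peaks of both no-competitor libraries were pooled, and peaks along a chromosome are not independent, so the interval is too narrow. No gene end share of these chromosomes from other libraries was set beside it. For the no-competitor peaks the tables argue against sites that the same antibody bound in the earlier experiment. Of those on chromosomes 9 and 13, 10.7% overlap an earlier H4Kacme peak, against 57.7% elsewhere. Neither share was computed for the peaks of H4Kacme-peptide replicate 2, so neither value decides what those peaks are. Without both chromosomes the retained share differed by -42.8 points and peak number by -7.52 on the log2 scale between the H4Kacme peptide and the 6 other libraries. What would raise the background there stays open, and no biological explanation was tested.

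The STL table lists 50 genes with a rate constant under 0.005, far below the median of 0.0466. The tables argue against few reads as the source, since the median was 9169 reads for these genes and 871 for the others. Reads of an annotated small RNA gene inside or within 1 kb may account for some: 12 of 50 (24%) hold one, against 803 of 7052 other genes (11.4%), an odds ratio of 2.46 (Fisher's exact two-sided p = 0.0116), as at C12orf57, which adjoins RNU7-1, and RCC1, which holds SNORA73A and SNORA73B. It accounts for at most those 12, and genes such as EIF3H (0.00146), COX6C (0.000413) and RAN (3e-04), chosen after their values were seen, hold none. These stay open, and no biological explanation was tested.

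The log2 ratio of Kacme to H4Kac peak number was 0.58 in HEK293T and -0.30 in K562, with every library of a line on the same side, and the difference between the lines was not tested. The share of peaks at gene ends, Kacme minus H4Kac, was -8.31 percentage points in HEK293T and 4.84 in K562, again with the libraries of each line apart. With lists of equal length the 2 values were 0.335 and 1.40, so the opposite directions ended, and the difference between the lines was not tested. Outside the main chromosomes, which no comparison used, lay 18.8% to 34.8% of the few peaks in the HEK293T pan-Kacme libraries with the H4Kacme peptide, against 10.2% and 16.7% in the inputs and at most 0.366% in the other libraries of that set. Regions in all 3 no-competitor and none of the 3 H4Kacme-peptide libraries of that set, or the reverse, numbered 3349. The highest of the other splits of these libraries gave 4, and with 1 of 10 splits reaching the real value the splits are too few for a share under 0.05. Every other split has an H4Kacme-peptide library on each side, and these libraries held 20, 45 and 39 peaks. Its number was therefore bound to be small, and the contrast adds nothing to the peak numbers.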

How the results depend on the processing

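The minimum fold of 4, the comparison of 1 heat-shocked with 1 untreated library, the T-to-C reads, the Kacme libraries of the second experiment in place of the first, and the leaving out of chromosome 1 or of chromosomes 9 and 13 were chosen only after the data were seen; the other alternatives were planned. Of 585 values of 67 main results under alternatives, 467 kept their direction and side of the threshold or stayed within the spread, 11 lost the call, 6 gained it, 87 moved and 14 changed sign. Of 738 values for 206 single genes and list tests, 635 stayed, 3 lost the call, 6 gained it, 82 moved and 12 changed sign. The alternative with every transcript start was not run because no transcript table with strand was used, and merging of peaks changes nothing because no list holds overlapping peaks. Where no construction is named below, the cause was not tested. Depth limits every list, since weak peaks pass or miss q with the number of reads.

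Shared regions depended on how a region is defined. With a -log10 q of 5 or more the shares were 82.1% (S2 H4Kac), 61.5% (HEK293T Kacme), 91.0% (K562 Kacme), 79.2% (K562 H4Kac) and 9.88% (second-experiment Kacme). With lists of equal length they were 81.2% (S2 H4Kac), 67.2% and 71.8% (HEK293T Kacme and H4Kac), 85.9% and 77.9% (K562) and 51.8% and 71.0% (second-experiment Kacme and H4Kacme). By summits within 250 bp they were 72.8% and 74.2% (S2 Kacme and H4Kac), 40.7% and 53.1% (HEK293T), 66.8% and 55.8% (K562) and 78.2% (H4Kacme). With 50% overlap K562 Kacme stood at 87.2%, and without input peaks H4Kacme at 96.7%. Leaving out 1 library gave 91.1% to 97.3% (S2 Kacme), 80.4% to 88.5% (S2 H4Kac), 33.7% to 65.7% (HEK293T Kacme), 52.2% to 85.4% (HEK293T H4Kac), 66.9% to 92.2% (K562 Kacme), 46.0% to 80.2% (K562 H4Kac), 7.85% to 19.1% (second-experiment Kacme) and 91.5% to 96.4% (H4Kacme). Regions then rest on a single library of that group, which shows the cause of the wider range. Without chromosome 1 the HEK293T shares were 57.5% and 80.1%.

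With the replicate block, that is, within equal replicate numbers, the shares were 84.3% (S2 H4Kac), 39.8% and 61.4% (HEK293T Kacme and H4Kac), 71.1% and 55.2% (K562) and 12.7% (second-experiment Kacme). In the HEK293T pan-Kacme competition the replicate block gave the same differences, -64.5 points and -7.99 on the log2 scale, with an adjusted exact p of 0.0625, because fewer assignments exist. Of 41 values with the block 33 stayed, 2 lost the call and 6 moved. Peak presence gave no sign that equal numbers pair the samples of that set. Its Pearson correlations over merged regions, as deviations from group means, ran from -0.0191 to 0.0401 in 9 pairs of equal number and from -0.0279 to 0.0288 in 18 other pairs. Such correlations leave out the level of a library, so a shared depth would not show. Replicate 3 held the most peaks without competitor (11190) and with the H4Kac peptide (14821). Replicate 2 held the most with the H4Kpr (9539) and H4Kacme (45) peptides. For gained, lost and single-line genes the block gives the same definition and no separate value.

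Of the gene end results, the HEK293T difference between Kacme and H4Kac turned to 0.335 points with lists of equal length (exact adjusted p = 0.667), and was -4.73 with a -log10 q of 5 or more and -5.30 with a 2 kb window. The K562 difference was 1.40 with lists of equal length. Genes in K562 alone numbered 1287 (Kacme) and 1849 (H4Kac) with a -log10 q of 5 or more, against 826 and 1130. List tests past 0.05 for Kacme numbered 6 to 8 when 1 library was left out, against 5. Neuronal genes of HEK293T Kacme alone gained the call without either HEK_Kacme replicate or K562_Kacme replicate 2, and C2H2 zinc finger genes of H4Kac alone gained it with a -log10 q of 5 or more in both lines (-5.12 and 7.52 points) and with lists of equal length in K562 (3.95). TIGAR turned to -1 libraries (HEK293T minus K562) with a 250 bp window. The calls for SOX1, LTBR, GPR4, RNF151 and FBXO46 ended with 250 bp and 2 kb windows, that for CD14 with 250 bp and those for PTPN7 and TMPO with 2 kb, and GFI1B turned from 0 to -1 libraries (HEK293T minus K562) with 250 bp, since a narrow window drops peaks and a wide window adds them. Differences of a list from other genes, in percentage points, turned for histone genes of K562 Kacme alone to -1.08 (-log10 q of 5 or more) and -2.62 (2 kb window), and for other blood genes of HEK293T Kacme alone to -0.930 (-log10 q of 5 or more), -2.73 (250 bp), -5.32 (2 kb) and -1.54 to -0.194 with 1 library left out. With 1 library left out they ran from -1.31 to 9.20 for neuronal genes of K562 H4Kac alone and from -6.50 to 1.90 for other blood genes of HEK293T H4Kac alone, and none of the values with the turned sign passed the test.

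After heat shock, with a fold of at least 4, 114 Kacme regions were gained and 930 lost, and 141 and 116 for H4Kac, by construction fewer. With a -log10 q of 5 or more 116 Kacme and 481 H4Kac regions were gained. With lists of equal length 1564 Kacme regions were lost and 378 H4Kac regions gained. By summits within 250 bp 1390 Kacme regions were gained, and 2474 H4Kac regions gained and 1983 lost. With 1 library left out the ranges were 450 to 6187 gained and 2608 to 6119 lost for Kacme, and 884 to 2466 gained for H4Kac, since fewer libraries then define a region. With 1 heat-shocked against 1 untreated library Kacme gained 6509 and 6607 and lost 3717 and 3417 regions in replicate 1, and gained 800 and 917 and lost 7596 and 7342 in replicate 2. H4Kac gained 1529 and 1649 and lost 1676 and 1706 in replicate 1, and gained 2613 and 2769 and lost 1871 and 1931 in replicate 2. The log2 ratio of Kacme peak number ran from -1.20 to 0.66.

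For STL-seq, the Kacme rho with the rate was -0.0190 with a -log10 q of 5 or more and -0.0258 above the 25th percentile, and the Kacme median difference -0.00207 with a 2 kb window, and these calls were lost. The Kacme median difference was -0.00235 with a 250 bp window. For H4Kac the median difference was -0.00111 without replicate 1 and -0.00143 with a 2 kb window, and the rho -0.00424 with a -log10 q of 5 or more. H4Kac gained the call for the median difference with a -log10 q of 5 or more (-0.00185) and a 250 bp window (-0.00222), and for rho with a 250 bp window (-0.0296), a 2 kb window (-0.0274) and -log10 p in place of fold (-0.0296). Its rho with STL reads was -0.00728 with a -log10 q of 5 or more, -0.0116 with a 250 bp window, and 0.0330, past the threshold, with -log10 p. With T-to-C reads the nascent values were 2.43 and 0.312 for Kacme and 1.88 and 0.215 for H4Kac, with every call as before.

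In the HEK293T pan-Kacme competition, with 1 library left out, the H4Kacme peptide differed from all others by -67.5 to -62.1 points and -8.22 to -7.64 on the log2 scale. Against no competitor, and with 1 library left out, the H4Kac peptide ran from -5.78 to 10.3 points and -0.22 to 0.45 on the log2 scale, and the H4Kpr peptide from -0.307 to 13.2 points and -0.0125 to 0.49. With the H4Kacme antibody the H4Kac peptide ran from -2.75 to 6.17 points and -0.52 to 0.0618 on the log2 scale, and stood at 0.0497 with a -log10 q of 5 or more. In S2 cells the H4Kac peptide ran from -0.77 to 0.20 on the log2 scale. Differences of the H4Kac and H4Kpr peptides from no competitor could not pass 0.05, since the smallest exact p is 0.1 for 3 libraries against 3 and 0.333 for 2 against 2. Genes marked in all replicates of the HEK293T pan-Kacme set, with 1 library left out, numbered 3212 to 4570 without competitor, 3388 to 4532 with the H4Kac, 4488 to 4839 with the H4Kpr and 2 to 3 with the H4Kacme peptide, since fewer libraries then have to agree.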

Other observations

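The tests of the X chromosome share and the look at olfactory receptor genes near the globin genes were chosen only after the results were seen.

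Kacme regions lost after heat shock of S2 cells lay on the X chromosome more often than regions that kept a peak in at least 1 heat-shocked library, called kept here. In all 4 libraries 2118 regions had a peak, so most kept regions lacked one in a heat-shocked library. Of 2589 lost regions 704 (27.2%) were on X, against 685 of 5676 kept regions (12.1%; Fisher's exact two-sided p = 1.85e-61), and 44 of 416 gained regions (10.6%). The share among lost regions was 19.2% against 10.0% without heat-shocked replicate 1 and 27.2% against 12.0% without heat-shocked replicate 2. For H4Kac 244 of 959 lost regions (25.4%) were on X, against 16.7% of kept regions (Fisher's exact p = 2.29e-10), and 22.3% of gained regions. Regions along a chromosome are not independent, so these p-values are too small as a measure of chance. Lost Kacme regions also lay lower in the list of untreated replicate 1 (median percentile 37.4) than kept regions (66.0), and the heat-shocked libraries were shallower. Lost and kept regions were not matched for peak strength, so weaker peaks on X cannot be told apart from a loss there.

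The 7 olfactory receptor genes marked by Kacme in both K562 replicates and neither HEK293T replicate were OR2AT4, OR2L13, OR2V1, OR51B5, OR51T1, OR52A1 and OR52A5. Of these OR51B5 (chromosome 11, 5340318 to 5505652), OR51T1, OR52A1 and OR52A5 lie in the same stretch of chromosome 11 as the fetal globin gene HBG1 (5248269 to 5249857), which was also marked in K562 alone. H4Kac in K562 alone added OR2A25, OR2A42, OR2B11 and OR52N2.

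Chromosome 1 held 19.8 ± 0.504% of Kacme and 21.9 ± 1.48% of H4Kac peaks in the first HEK293T experiment, against 11.2 ± 0.0374% of Kacme peaks in the second and 14.1 ± 0.140% in K562 (SD, n = 2). Among inputs of the second experiment 56% and 62.3% of peaks lay on chromosome 1.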
